A study of Mus musculus with 4 samples.

How the data were processed

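RNA from primary mouse colonic epithelial cells of 2 genotypes, each without and with 20 ng/ml LIF, was sequenced after the cells had attached for 24 h. The table held 1 column of values for each of the 4 groups, and 0 value columns were left unused. The design text mentions duplicates, but the labels list 1 sample per group, and whether a column is a single library or pooled duplicates is not stated. Per the labels, libraries were made from total RNA with a TruSeq RNA kit. Reads were aligned with HISAT and Bowtie2 to mm10, per the submitters' processing notes; versions, the program that computed expression and its annotation are not given in the sources used here. The deposited values are FPKM with 2 decimals, per the file headers, and only genes above 0 in at least 1 library are listed. The table held 17604 genes. Of its symbols, 26 had been turned into dates by a spreadsheet, and these were kept as listed. No gene of the mitochondrial genome was listed.

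Depth was estimated from the FPKM values, since the table holds no counts. In genes with 1 transcript of 300 to 1500 bases, low FPKM values fall on steps of whole fragments over transcript length, which gave 24.0, 22, 22.8 and 27.5 M fragments (M for mega) for wild-type control, wild-type LIF, Stat4-/- control and Stat4-/- LIF from 108, 117, 119 and 88 genes. At these depths, 61.1, 54.7, 58.8 and 62.5% of the values lay within 0.15 fragments of a whole number. The depths were chosen for closeness to whole numbers, which raises these shares. A score of that closeness was 0.435, 0.450, 0.464 and 0.433, against at most 0.313, 0.355, 0.339 and 0.287 with lengths shuffled between genes. With 150 to 250 bases taken off the lengths, the best depths ran from 20.9 to 57.4 M, at scores of at most 0.343. The depths are therefore approximate. A single fragment on a transcript of 2 kb corresponds to 0.0208, 0.0227, 0.0219 and 0.0182 FPKM in the same order, and this covers counting error only.

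Genes with a mean FPKM over the 4 libraries of at least 1 were tested (12274 genes). Differences were taken on log2(FPKM + 1) for 5 contrasts: LIF against control in each genotype, Stat4-/- against wild type in each treatment, and the difference of the LIF effects. With 1 library per group these have no test, and genes were counted at a difference of at least 1 (2-fold). A limma fit (version 3.58.1 in R 4.3.3) with genotype and treatment as additive terms and a mean-variance trend tested the LIF effect and the genotype effect, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. That fit has 1 residual degree of freedom and a prior of 10.2, and it counts any interaction as error. On simulated data for the LIF effect, with 200 of 12274 genes changed (100 per size), it recovered 50% of genes changed by 0.3 and 100% of genes changed by 1 on the log2 scale, with 13 false calls among 163. The simulated noise was normal, with the same spread for all genes of similar expression. Real genes of similar expression can differ in spread, so these rates may be better than those in the real data.

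Before the data were examined, 35 gene lists were fixed: gp130-STAT3 targets, LIF receptor and JAK-STAT components, YAP-TEAD, fetal-like regeneration, stem, absorptive, goblet, enteroendocrine, tuft, general epithelium, tight junction, antimicrobial and acute phase, inflammatory cytokines and NF-kB, interferon response, MHC class I and class II, cell cycle, unfolded protein response, immediate early and heat shock, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, fibroblast, smooth muscle, endothelium, macrophage, neutrophil, T and NK, B and plasma, mast, enteric glia and neuron, red blood cell, sex-linked genes and chromosome 1 neighbours of Stat4. For lists with at least 4 tested members, the median difference was set beside 10000 random lists of the same size matched on mean FPKM in 20 bins, as a description of these libraries. Limma counts are given over all genes and adjusted over the list alone.

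The genes named were chosen by a rule fixed in advance. It took a fixed set of pathway genes that included Stat4, Stat3, Lif, Lifr, Il6st, Socs3 and Yap1, the 10 highest and 10 lowest genes of each contrast with a mean of at least 5 FPKM (without predicted genes and small RNAs), up to 4 members per list and contrast with the largest difference, the 10 highest and 10 lowest limma calls by coefficient, and genes past the size rule under LIF in both genotypes. Other list members named as calls, and the Y-linked and Oas1, Sprr2a and Tmem254 family members, were chosen after their values were seen. Positions and transcript sequences came from GENCODE M21 (mm10), in which 96.98% of tested symbols matched once. The share of a gene's 31-base words found in another listed gene measured how far reads could be shared.

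The alternatives tried were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, median-of-ratios scaling, upper-quartile scaling, quantile normalization, limma without a variance trend and a 1.5-fold size rule. Leaving out genes that share over 50% of their words with another gene was added after the data were seen. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Reads were not used here.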

Results

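Gene expression was measured by RNA sequencing in intestinal epithelial cells isolated from the colon of wild-type mice and of Stat4-/- mice, which lack a transcription factor activated by cytokine receptors. The cells were plated on Matrigel, left to attach for 24 h and kept without or with 20 ng/ml of leukemia inhibitory factor (LIF), a cytokine of the interleukin-6 family that signals through LIFR and gp130. The labels give no duration of LIF exposure for a sample. The 4 groups were wild-type control, wild-type LIF, Stat4-/- control and Stat4-/- LIF, with 1 library each. A difference between single libraries therefore has no replicate check, and no p-value is given for it. The comparisons ask which genes differ with LIF, which differ with Stat4 genotype, and whether the LIF response differs without Stat4. The deposited table listed 17604 genes in FPKM, the density of sequenced fragments normalised for transcript length and library size. Of these, 12274 had a mean of at least 1 over the 4 libraries and were tested. The estimated depth was 24.0 M fragments (M for mega) for wild-type control, 22 M for wild-type LIF, 22.8 M for Stat4-/- control and 27.5 M for Stat4-/- LIF.

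Stat4 (ENSMUSG00000062939, chromosome 1, 51987148 to 52107189 in mm10) was measured at 19.7 FPKM in the wild-type control library and 20.5 FPKM in the wild-type LIF library. In the Stat4-/- libraries it stood at 2.01 FPKM without and 2.98 FPKM with LIF, which is 9.81-fold and 6.87-fold lower, so the targeted gene goes with the genotype labels. The LIF receptor gene Lifr was at 4.79, 4.14, 4.89 and 4.80 FPKM in wild-type control, wild-type LIF, Stat4-/- control and Stat4-/- LIF. In the same order, Il6st, which encodes gp130, was at 62.3, 61.9, 68.7 and 69.0 FPKM, and Stat3, the main transcription factor downstream of gp130, at 55.9, 61.2, 66.1 and 65.6 FPKM. Lif itself was expressed at 41.8, 45.4, 63.8 and 63.6 FPKM.

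**Figure D1:**
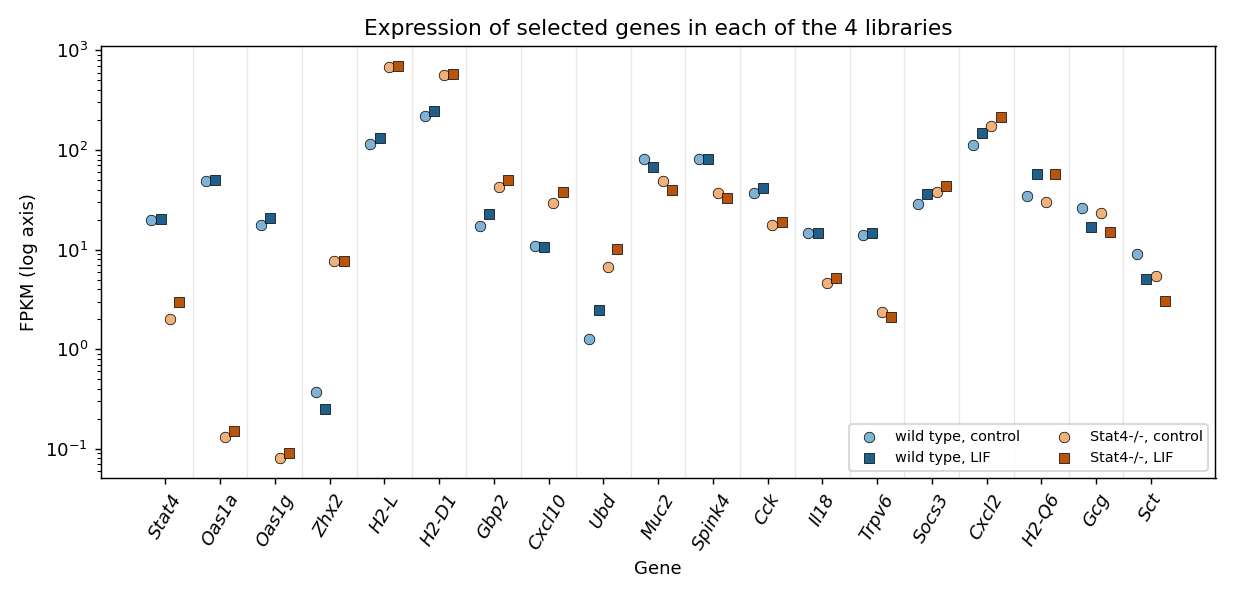
FPKM on a log axis of 19 genes in the 4 libraries, each point being 1 library; circles are control and squares LIF libraries, blue is wild type and orange Stat4-/-, and the genes were picked for display after their values were seen. Stat4 lies near 20 FPKM in both wild-type libraries and at 2.01 and 2.98 FPKM in the Stat4-/- libraries, while Gcg and Sct lie lower in the LIF library of each genotype.

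In wild-type cells the LIF library differed little from the control library. Among 12274 genes, 8 were at least 2-fold higher and 8 at least 2-fold lower on the log2(FPKM + 1) scale. Of the genes with a mean of at least 5 FPKM, Cd52, a leukocyte surface glycoprotein, showed the highest difference (4.59 FPKM in control, 13.1 FPKM with LIF). It was followed by Rpl37rt (6.89 and 13.9 FPKM), Pdlim4 (6.56 and 12.7 FPKM) and the MHC class I gene H2-Q7 (13.3 and 23.6 FPKM). Lsm5, Phf11b, Hbb-b1, Ifitm1 and Bola1 came next, with log2 differences between 0.73 and 0.75, and the MHC class I gene H2-Q6 (34.4 and 57.3 FPKM) was last of the 10 highest. Tmem254b ranked lowest (10.9 FPKM in control and listed at 0 with LIF), but all of its 31-base words are shared with other genes, its copy Tmem254c went from 0.01 to 9.23 FPKM, and the sum of the family went from 11.2 to 9.23 FPKM. Next came Sct, which encodes the hormone secretin (9.10 and 5.07 FPKM), Bcl2l15 (9.95 and 5.74 FPKM) and Gcg, which encodes proglucagon (26.2 and 16.7 FPKM). Ptar1, Hist1h4i, Bik, Vkorc1, Gpihbp1 and Defa17 followed, with log2 differences from -0.62 to -0.54. Defa17 and Phf11b share 93.2 and 62.9% of their words with other genes.

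By gene list, genes of gp130-STAT3 signalling were slightly higher in the wild-type LIF library, with 22 of 27 members above 0 and a median log2 difference of 0.12, which 2 of 10000 expression-matched random lists reached. Socs3, the feedback inhibitor of gp130 signalling, was at 28.7 and 36.2 FPKM, Socs1 at 4.37 and 6.16 FPKM, and the antimicrobial lipocalin gene Lcn2 at 10.5 and 15.0 FPKM. Interferon-response genes had a median of 0.16 (26 of 30 above 0), MHC class II genes 0.33 (6 of 7), MHC class I genes 0.18 (12 of 13), immediate early and heat shock genes 0.15 (17 of 20), and genes of the unfolded protein response 0.14 (18 of 19). At most 2 of 10000 random lists reached any of these medians. Genes of cholesterol synthesis were lower (18 of 22 below 0, median -0.16, reached by 0 random lists), as were enteroendocrine genes (8 of 12, median -0.15, reached by 6 random lists). In Stat4-/- the cholesterol list had a median of -0.05, at or below which lay 1238 random lists. Limma called 0 of its 22 genes for the LIF effect common to both genotypes (4 lower adjusted over the list alone). Targets and components of the YAP-TEAD pathway had a median of -0.05 (17 of 24 below 0), with Yap1 at 33.7 and 35.0 FPKM. Macrophage markers (11 of 17 above 0, median 0.10, reached by 240 random lists) and T and NK cell markers (5 of 8, median 0.15, reached by 340) were also slightly higher. The percentiles describe these libraries and are not tests. Of the genes past the 2-fold rule, 12 had a mean under 5 FPKM, and without genes that share over 50% of their 31-base words with another listed gene, an alternative added after seeing the data, the counts were 3 higher and 1 lower.

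In Stat4-/- cells the LIF and control libraries were as close, with 8 genes at least 2-fold higher and 7 at least 2-fold lower. With a mean of at least 5 FPKM required, these counts were 2 and 1. Highest and lowest genes are given within that limit, without predicted genes and small RNAs. The highest were Defa20, a Paneth cell defensin gene (2.56 and 11.6 FPKM), the hemoglobin gene Hba-a2 (2.95 and 7.20 FPKM), H2-Q6 (30.0 and 57.1 FPKM), Sprr2b (7.38 and 13.5 FPKM) and the B cell receptor component Cd79a (6.50 and 11.3 FPKM). Ebag9, Srek1ip1, Mcpt2, Ccl11 and Tgtp2 followed at log2 differences of 0.59 to 0.63. The lowest were Rpl37rt (11.9 and 4.6 FPKM), Rep15 (5.74 and 2.66 FPKM), the fatty acid receptor gene Ffar4 (6.71 and 3.48 FPKM) and clusterin, Clu (170 and 99.1 FPKM), and then Dmpk, Msln, Igsf23, Ppp1r14a, Sct and Arl3 at -0.76 to -0.67. Defa20, Hba-a2 and Tgtp2 share over 90% of their 31-base words with other listed genes, so their values are uncertain.

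Interferon-response genes were again higher with LIF in Stat4-/- cells (27 of 30 above 0, median 0.16), together with MHC class II genes (6 of 7, median 0.36) and inflammatory cytokine genes (19 of 23, median 0.13), each median being reached by at most 1 of 10000 random lists. Cxcl1, a neutrophil chemokine gene, was at 358 and 469 FPKM, and Cxcl2 at 173 and 214 FPKM. MHC class I genes had a median of 0.12 (12 of 13), unfolded protein response genes 0.12 (18 of 19) and immediate early genes 0.09 (19 of 20). The gp130-STAT3 list had a median of 0.04 (18 of 27 above 0), which 1056 of 10000 random lists reached; Socs3 was at 38.0 and 43.8 FPKM. Enteroendocrine genes were lower (10 of 12, median -0.27), among them Gcg (23.2 and 15.1 FPKM) and Pyy (41.3 and 27.7 FPKM), as were genes of absorptive colonocytes (17 of 24, median -0.15), glycolysis and hypoxia (21 of 22, median -0.15) and goblet cells (12 of 18, median -0.12). At most 4 of 10000 random lists lay as low as any of these 4 medians. With a mean of at least 5 FPKM required, the absorptive median was -0.04. Markers of B and plasma cells (7 of 8 above 0, median 0.62, reached by 0 random lists) and of T and NK cells (7 of 8, median 0.30, reached by 4) were higher by more than the interferon list, though the T and NK median was -0.05 with a mean of at least 5 FPKM. Red blood cell genes were also higher (3 of 4 above 0, median 0.34, reached by 5 random lists). Smooth muscle genes were lower (9 of 12 below 0, median -0.13, at or below which lay 13 random lists).

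The LIF response common to both genotypes was tested with limma, with 2 LIF libraries set against 2 control libraries and genotype as a block. It called 86 genes higher and 15 lower at a Benjamini-Hochberg adjusted p under 0.05, and the median size of the calls was 0.29 on the log2 scale. H2-Q6 rose by 0.81 (SE 0.060, adjusted p = 0.000156), Cxcl2 by 0.35 (adjusted p = 0.0088) and Cxcl1 by 0.31 (adjusted p = 0.00953), each higher with LIF in 2 of 2 genotypes. Gcg fell by 0.61 (SE 0.066, adjusted p = 0.00614) and Sct fell by 0.71 (SE 0.103, adjusted p = 0.0205), each lower with LIF in 2 of 2 genotypes. Other genes among the 10 highest were Hist1h4a, Cd52, Gvin1, Hbb-b1, Ubd, Pdlim4, Ccl21a, Fcer1g and Ifitm1, and other genes among the 10 lowest were Bglap, Hist1h1d, Igsf23, Clu, Clca3a2, Bmp8b and Dcdc2c. Of these, Gvin1 shares 99.5% and Bglap 80.5% of their 31-base words with other genes, and H2-Q6 shares 49%. Sprr2a2 had the lowest coefficient (-3.02), going from 6.99 and 7.69 FPKM to 0.03 FPKM in each LIF library, but it shares 97.8% of its 31-base words with other genes, and the summed FPKM of Sprr2a1, Sprr2a2 and Sprr2a3 went from 1899 to 1979 in wild type and from 1413 to 1213 in Stat4-/-. The count depended on the processing: median-of-ratios scaling gave 7 higher and 3 lower, quantile normalization 1 higher and 3 lower, and a fit without a variance trend or without the filter on low values gave 0 higher and 1 lower. With 1537 genes at an unadjusted p under 0.05 with the variance trend and 1100 without it, most differences did not pass the adjustment. Sprr2a2 alone passed in every fit it entered, whereas H2-Q6 and Gcg each passed in 5 of 7 alternative fits, Cxcl2 in 4, Cxcl1, Sct, Ifit3, Gbp3 and Zbp1 in 3, and Cebpd, Muc2, Gbp2 and Clu in 2.

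Among the lists, 1 of 27 gp130-STAT3 targets rose (Cebpd, by 0.28, adjusted p = 0.0313), and 8 did adjusted over the list alone. Socs3 did not pass (0.26, SE 0.058, adjusted p = 0.0675). Interferon-response genes gave 6 risen of 30 (15 adjusted over the list alone), among them Ifit3, Gbp2, Gbp3 and Zbp1. MHC class I genes gave 3 of 13 (10 adjusted over the list alone), MHC class II genes 2 of 7 (5), B and plasma cell genes 0 of 8 (5; median coefficient 0.38), macrophage genes 2 of 17 (2, with 1 lower), inflammatory cytokines 5 of 23 (10), unfolded protein response genes 3 of 19 (9) and immediate early and heat shock genes 2 of 20 (11). Of 25 cytosolic ribosomal protein genes, 7 rose (23 adjusted over the list alone), with a median coefficient of 0.12. Of 12 enteroendocrine genes 2 fell, Gcg and Sct (6 adjusted over the list alone), and of 18 goblet cell genes Muc2 fell, from 81.0 to 68.0 FPKM in wild type and from 48.9 to 39.6 FPKM in Stat4-/- (3 fell and 1 rose adjusted over the list alone). No member of the list of LIF receptor and JAK-STAT components passed, with 0 of 23 called by limma over all genes and 0 adjusted over the list alone. The YAP-TEAD list had 0 calls over all genes and 1 lower adjusted over the list alone.

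Whether the LIF response differs between genotypes could not be tested, since the difference of the LIF effects leaves 0 residual degrees of freedom. As values, 18 genes had a LIF effect at least 2-fold higher in Stat4-/- than in wild type and 24 at least 2-fold lower. With a mean of at least 5 FPKM required, these counts were 2 and 4, and the genes named next were ranked within that limit, without predicted genes and small RNAs. The highest were Tmem254b (3.50), Defa20 (1.84), Ggact (0.88), Tram2 (0.82) and Hba-a2 (0.80), followed by Ptar1, Rpa2, Bcl2a1d, Vkorc1 and Defa17. The value of Tmem254b follows its exchange with Tmem254c in the wild-type libraries, as the Tmem254 sums of 11.2, 9.23, 10.6 and 10.5 FPKM show, and Defa20, Hba-a2, Defa17 and Bcl2a1d share 91.9, 91.0, 93.2 and 89.1% of their words with other genes. The lowest were Rpl37rt (-2.12), Prelid2 (-1.03), the neuropeptide gene Npy (-0.98), Rep15 (-0.96) and Phf11b (-0.94), followed by Ppp1r14a, Cd52, Ift43, Mrpl55 and Ccdc90b. Genes of glycolysis and hypoxia were slightly higher with LIF in wild type (17 of 22 above 0, median 0.07) and lower with LIF in Stat4-/- (21 of 22 below 0, median -0.15), a difference of -0.21 that 0 of 10000 random lists matched. Examples are the glycolytic enzyme gene Tpi1, at 308 and 324 FPKM in wild type and 344 and 274 FPKM in Stat4-/-, and Bnip3, at 26.5 and 29.5 FPKM and then 31.4 and 22.8 FPKM. The gp130-STAT3 list had a median difference of -0.09, at or below which lay 11 of 10000 random lists. This list was already higher in Stat4-/- without LIF, with a median genotype difference of 0.24 in the control libraries and 0.10 in the LIF libraries. With 1 library per group, a weaker LIF response cannot be told apart from a higher level in that control library. B and plasma cell genes had the highest list median, 0.49, which 0 random lists reached. Interferon-response genes differed by a median of -0.02.

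Across the 12274 genes, which are not replicates, the LIF effects of the genotypes had a Pearson r of 0.16 and a Spearman rho of 0.19, and 58.6% had the same sign; no library is shared between these effects. Only Sprr2a2 passed the 2-fold rule in the same direction in both, against 0.0098 genes expected of independent lists. By the 1.5-fold rule 4 genes were higher in both, against 0.317 expected, and 5 lower in both, against 0.194. These expected numbers take all genes as equally likely to pass, so an excess over them does not by itself show a shared response. Of the sum of squares across genes, the LIF contrast held 21.1%, the genotype contrast 63.5% and their interaction, which serves as error in the limma fit, 15.4%.

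Without LIF, the Stat4-/- library differed from the wild-type library more than LIF changed either, with 39 genes at least 2-fold higher and 35 at least 2-fold lower. The highest and lowest genes named next are those with a mean of at least 5 FPKM, without predicted genes and small RNAs. The highest were H2-L, an MHC class I gene (115 FPKM in wild type, 685 FPKM in Stat4-/-), Ubd (1.27 and 6.64 FPKM), H2-Q7 (13.3 and 37.6 FPKM), H2-D1 (219 and 562 FPKM), the chemokine gene Cxcl10 (11 and 29.2 FPKM), Gbp2 (17.2 and 42.3 FPKM), Gbp2b (14.5 and 35.6 FPKM) and the immunoproteasome gene Psmb9 (7.55 and 19.0 FPKM), together with the smooth muscle gene Cnn1 (10.5 and 31.3 FPKM) and Cd52 (4.59 and 12.7 FPKM). The lowest were Oas1a, an antiviral oligoadenylate synthetase gene (48.7 and 0.13 FPKM), Oas1g (17.8 and 0.080 FPKM), Stat4, the immunoglobulin joining chain gene Jchain (25.6 and 4.64 FPKM), the calcium channel gene Trpv6 (14.2 and 2.38 FPKM), Defa20, Ly6c2 (9.03 and 1.68 FPKM), the cytokine gene Il18 (14.5 and 4.58 FPKM), Bcl2l15 and Igsf23. The wild-type libraries also held Y-linked transcripts that the Stat4-/- libraries nearly lacked, with Ddx3y at 5.86 and 0.050 FPKM and Eif2s3y at 6.68 and 0.020 FPKM in the control libraries.

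With LIF, the genotypes differed in much the same way, with 36 genes at least 2-fold higher in Stat4-/- and 56 at least 2-fold lower. Genes were again ranked among those with a mean of at least 5 FPKM, without predicted genes and small RNAs. Apart from Tmem254b, the highest were H2-L (133 and 704 FPKM), Cxcl10 (10.6 and 38.3 FPKM), Ubd (2.5 and 10.1 FPKM), the interferon-inducible GTPase genes Iigp1 (11.5 and 31.3 FPKM), Gbp4, Tgtp2 and Gbp5, Cd79a (3.87 and 11.3 FPKM) and H2-D1 (246 and 585 FPKM). The lowest were Oas1a (50.3 and 0.15 FPKM), Oas1g (20.9 and 0.090 FPKM), Jchain (25 and 3.50 FPKM), Stat4, Trpv6 (14.6 and 2.13 FPKM), Ly6c2, Igsf23, Rpl37rt, Il18 (14.8 and 5.14 FPKM) and Rep15. The genotype differences without and with LIF, which share no library, had a Pearson r of 0.61 and a Spearman rho of 0.53 across genes. In both treatments 14 genes were at least 2-fold higher, against 0.11 expected of independent lists, and 20 at least 2-fold lower, against 0.16. The 2 libraries of a genotype may come from the same animals or culture, so these 2 contrasts may not be independent. Their overlap is therefore no replication of an effect of Stat4.

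**Figure D2:**
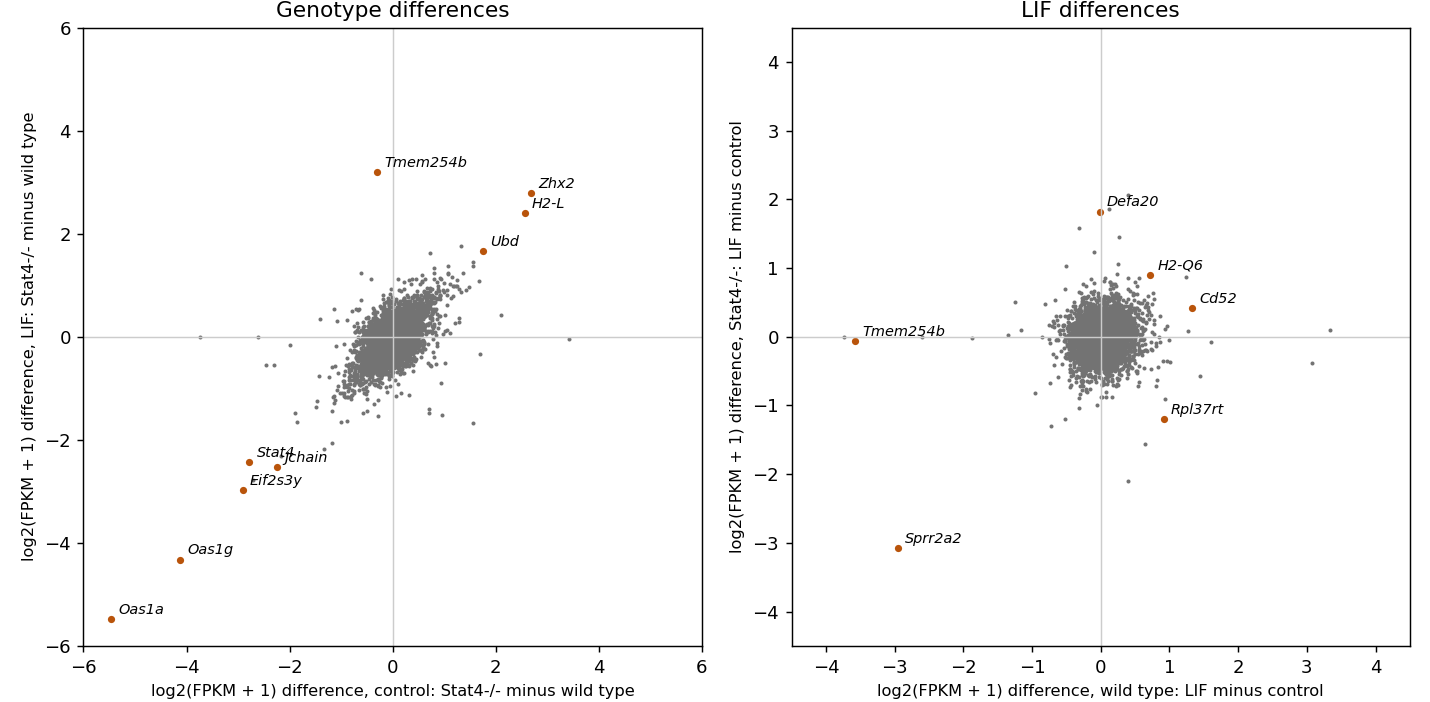
Differences of log2(FPKM + 1) for the 12274 tested genes, each point being 1 gene; the left plot sets the genotype difference without LIF (x) against that with LIF (y), the right plot the LIF difference in wild type (x) against that in Stat4-/- (y), and named genes are in orange. Genotype differences line up between treatments (r = 0.61), whereas LIF differences hardly do (r = 0.16).

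All 4 samples carry the strain label C57BL/6. The genotype difference common to both treatments was tested with limma (2 Stat4-/- libraries against 2 wild-type libraries, treatment as a block), which called 959 genes higher and 943 lower in Stat4-/- at an adjusted p under 0.05. Interferon-response genes rose almost as a whole: 29 of 30 were higher and only Oas1a was lower (the same counts adjusted over the list alone), with a median coefficient of 0.62. Cxcl10 rose by 1.55 (SE 0.092, adjusted p = 1.15e-06), Gbp2 by 1.18 (SE 0.062, adjusted p = 4.07e-07) and Ifit3 by 1.03. MHC class I genes rose in 11 of 13 cases (12 adjusted over the list alone), with H2-D1 up by 1.30 (SE 0.038, adjusted p = 3.13e-09) and the peptide transporter gene Tap1 by 0.86, and MHC class II genes in 5 of 7 (5 adjusted over the list alone), with H2-DMb2 up by 1.47. Of 23 inflammatory cytokine and NF-kB genes 11 rose and Il18 fell (13 and 1 adjusted over the list alone), with Il6 up by 0.85 (SE 0.055, adjusted p = 2.01e-06) and Csf3 by 0.79. Of 19 genes of the unfolded protein and integrated stress response 16 rose (17 adjusted over the list alone), among them Sdf2l1 by 0.58. Of the gp130-STAT3 targets 9 rose, including Socs3 (0.33, adjusted p = 0.00282), Cebpd and Icam1, and 2 fell (14 and 2 adjusted over the list alone). Lif rose by 0.54 (SE 0.053, adjusted p = 5.28e-05), as did Stat2, Il6 and Il11 among 23 LIF receptor and JAK-STAT components, of which Stat4 fell (8 higher and 1 lower adjusted over the list alone).

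Some markers of epithelial cell types fell in Stat4-/-. Of 18 goblet cell genes 11 fell and Klk1 rose (12 and 1 adjusted over the list alone): Spink4 fell by 1.21 (SE 0.055, adjusted p = 2.05e-07), the mucin gene Muc2 by 0.74 (SE 0.049, adjusted p = 2.84e-06), and Tff3 and Zg16 fell too. Of 24 genes of absorptive colonocytes 14 fell and 2 rose (14 and 3 adjusted over the list alone), with the water channel gene Aqp8 going from 233 to 165 FPKM without LIF and from 267 to 160 FPKM with LIF. Of 12 enteroendocrine genes 5 fell, with Cck for cholecystokinin at 37.2 and 17.9 FPKM in the control libraries, and Scgn rose (7 and 1 adjusted over the list alone). Of 18 general epithelial genes 8 fell and 1 rose (11 and 2 adjusted over the list alone), but the keratin gene Krt18 was at 1191, 1154, 1274 and 1198 FPKM and was not called. Of 22 genes of cholesterol synthesis 12 fell (15 adjusted over the list alone), with Hmgcs1 at 43.8 and 28.8 FPKM and Cyp51 at 13.3 and 8.54 FPKM without LIF. Of 24 YAP-TEAD genes 4 fell, including the target genes Ctgf and Cyr61, and 3 rose, Yap1 by 0.21 (SE 0.055, adjusted p = 0.0237), Tead4 and F3 (7 and 3 adjusted over the list alone). Beside these groups, markers of smooth muscle (6 of 12 higher, 1 lower), endothelium (6 of 13 higher) and B cells (5 of 8 higher, with Jchain lower) also changed with genotype, and 20 of 25 ribosomal protein genes were higher. Adjusted over the list alone, the counts were 8 and 1 for smooth muscle, 9 for endothelium, 5 and 1 for B cells and 24 for ribosomal proteins. Whether the marker changes lie within cells or in the mix of cells cannot be told apart in these libraries. The list medians of the ribosomal genes were above 0 in all 4 contrasts, with 25 of 25 members above 0 in each, and quantile normalization brought the median with LIF from 0.14 to 0.04. The labels do not say whether the 2 libraries of a genotype came from different animals, so the limma p-values measure only the spread between these libraries. Without a variance trend, 0 calls were left in the lists of the unfolded protein response, ribosomal proteins, general epithelium, endothelium, YAP-TEAD, mast cells and red blood cells. In that fit 16 interferon-response, 9 inflammatory cytokine, 5 MHC class I, 3 MHC class II, 1 gp130-STAT3, 4 absorptive, 3 goblet, 2 enteroendocrine, 3 cholesterol, 2 smooth muscle and 3 B and plasma cell genes were called. Over all genes it called 123 genes higher and 128 lower, and a fit without the filter on low values 407 and 357; 221 of the calls passed in every fit they entered.

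**Figure D3:**
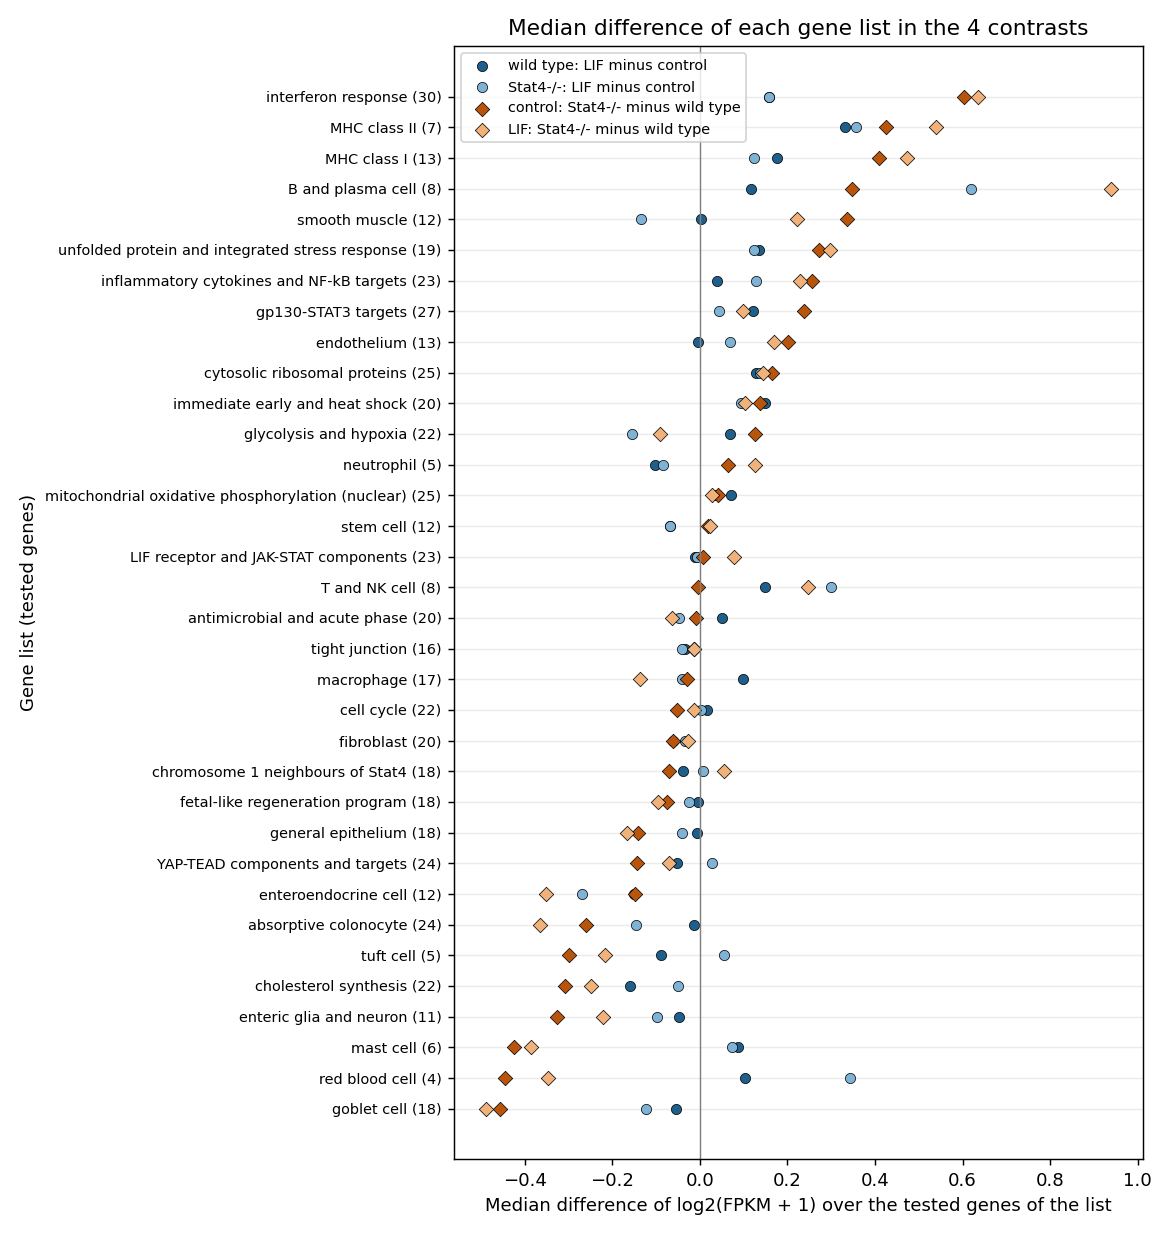
Median difference of log2(FPKM + 1) over the tested members of each gene list with at least 4 such members, with their number in brackets; circles are LIF minus control in each genotype and diamonds Stat4-/- minus wild type in each treatment, each computed from 2 libraries. Interferon-response genes lie at 0.60 and 0.64 for genotype and at 0.16 for LIF in each genotype, and goblet cell genes at -0.46 and -0.49 for genotype.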

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

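The tests on X-linked genes, Y-linked genes, depth, the Oas1 family sum, interferon genes without Oas1a, the chromosomes of the placed genes and 10-fold autosomal genes were chosen only after the result was seen, as was the split of shared LIF genes by near-identical copies.

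Rpl37rt, by its symbol a ribosomal protein gene, moved in opposite directions with LIF in the genotypes, by 0.92 in wild type and -1.20 in Stat4-/- on the log2 scale. The difference of -2.12 was not tested, because each value rests on 1 library per group. Its FPKM was 6.89 and 13.9 in wild type and 11.9 and 4.6 in Stat4-/-, and it shares 44.9% of its 31-base words with other listed genes.

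The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 15.95 and 16.7 FPKM in the wild-type libraries and to 0.080 and 0.19 FPKM in the Stat4-/- libraries, without and with LIF. Lower depth is argued against, since the wild-type libraries had 0.914 times the estimated depth of the Stat4-/- libraries. All 4 genes lay far under their wild-type FPKM in both treatments (ratios of at most 0.013), so male cells may be present in the wild-type libraries and nearly absent from the Stat4-/- libraries. Whether the wild-type cells came only from males cannot be told apart from a mixture, because 4 X-linked genes with a Y copy differed by a median of -0.0237 (range -0.24 to 0.13) and how far they escape X inactivation in these cells is not known. The labels give no sex of the animals, so genotype and sex are confounded here as far as these genes show.

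Oas1a and Oas1g were near 0 in both Stat4-/- libraries, while H2-L and Zhx2 were high there (Zhx2 at 0.37 and 0.25 FPKM in wild type and 7.77 and 7.62 FPKM in Stat4-/-). Reads moved to near-identical copies are argued against for Oas1, since the sum of 7 Oas1 genes fell by 3.69 on the log2 scale in the treatment with the smaller change, and lower interferon signalling is argued against because the other interferon-response genes had a median of 0.62 in the treatment with the lower one. A segment of another strain around Stat4 cannot hold Oas1a, Oas1g or Zhx2, since 0 of these 3 placed genes lie on its chromosome, but H2-L has no position in the annotation, and whether such a segment exists cannot be told apart: the 72 genes within 10 Mb lay at percentile 43.7 of neighbouring runs elsewhere (95% bootstrap interval 0.85 to 93.7), while 20.8% of them passed 0.05 against 15.6% of other placed genes. All 4 samples are labelled C57BL/6, and a strain difference elsewhere in the genome was not decided: the 4 genes placed on autosomes besides Stat4 that were at least 10-fold apart in both treatments are Oas1a, Oas1g and Zhx2, which are the pattern itself, and Defa3, which shares 92.6% of its words with other genes, and Ren2, as far apart, has no position (2.77 and 2.26 FPKM in wild type, 0.040 and 0.030 FPKM in Stat4-/-). H2-L, at 115 and 133 FPKM in wild type as well, decides nothing here, as reads of H2-D1 could be counted on it. Their sum was 334, 380, 1246 and 1289 FPKM in wild-type control, wild-type LIF, Stat4-/- control and Stat4-/- LIF. Exchange of reads between these 2 genes alone would leave the sum unchanged, but the sum does not tell which of them rose. Without sequence, a strain difference cannot be told apart from an effect of Stat4 loss, which stays open and untested. This doubt extends to every genotype difference reported.

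Of 30 genes past the 2-fold rule under LIF in at least 1 genotype, most share sequence with other genes or are weakly expressed. Among the 24 with a transcript sequence, 58.3% share over 50% of their words with another listed gene, against 2.0% of tested genes (Fisher's exact test, two-sided, p = 1.9e-18), so reads may be split differently between near-identical copies. Weak expression was also more frequent, as 76.7% had a mean under 5 FPKM, against 28.0% of tested genes (Fisher's exact test, two-sided, p = 4.23e-08). Whether few reads play a part is not settled by this. A single fragment on a 2 kb transcript is about 0.02 FPKM at the estimated depths, so a mean under 5 FPKM need not mean few fragments. Transcript length was not taken into account. A response of both genotypes cannot be told apart from shared copies or weak expression. By the 2-fold rule 1 gene, Sprr2a2, was shared in direction against 0.0098 expected, and 0 were shared among genes without near-identical copies. By the 1.5-fold rule 4 were higher in both (0.317 expected) and 5 lower in both (0.194 expected). These expected numbers take all genes as equally likely to pass, whereas genes with shared words or low means passed the 2-fold rule more often. An excess over them therefore does not show a shared response. For 4 of the 30, Rpl37rt, Cd52, Gm21498 and Gm15308, neither limit was passed. The share of words given above for Rpl37rt lies close under its limit, so shared reads are not excluded for it.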

How the results depend on the processing

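The alternative without genes that share words with another gene was chosen only after the result was seen.

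The counts of genes in each direction moved most. With a pseudocount of 0.1, 38 genes were higher and 22 lower with LIF in wild type, 29 and 38 with LIF in Stat4-/-, 88 and 90 by genotype without LIF, 87 and 118 by genotype with LIF, and 69 and 104 for the difference of LIF effects; limma called 32 and 5 for LIF. With no filter the difference of LIF effects gave 29 and 42, limma 0 and 1 for LIF and 407 and 357 for genotype. With a mean of at least 5 FPKM the same 5 contrasts gave 3 and 1, 2 and 1, 23 and 16, 17 and 25, and 2 and 4, because fewer genes were tested. The 1.5-fold rule gave 72 and 35, 54 and 68, 199 and 195, 197 and 270, and 130 and 200, as a lower limit must. Without genes that share words the counts were 3 and 1 (LIF in wild type), 4 and 2 (LIF in Stat4-/-), 23 lower (genotype without LIF) and 8 and 12 (difference of LIF effects), with fewer genes counted. Median-of-ratios scaling gave 7 and 3 limma calls for LIF and quantile normalization 1 and 3. Without a variance trend limma gave 0 and 1 for LIF, with 1100 genes at an unadjusted p under 0.05, and 123 and 128 for genotype. Where no reason is given, the cause was not tested.

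Among list results with a main median of at least 0.1 in size, 6 changed sign with a mean of at least 5 FPKM, under which fewer members were tested. They were neutrophil genes by genotype with LIF (-0.11), T and NK genes with LIF in Stat4-/- (-0.0494) and by genotype with LIF (-0.51), B and plasma genes by genotype without LIF (-0.72) and with LIF (-0.60), and red blood cell genes for the difference of LIF effects (-0.27).

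The other 71 values of comparisons stayed within a factor of 1.5 of the main value. The correlation of the LIF effects lay between 0.131 and 0.225, the genotype share of the sum of squares between 59.6 and 70.0%, and the genotype calls under the other 5 alternatives between 674 and 997 higher and between 683 and 936 lower. Of the list medians and named genes, 2421 values counted as the same, meaning a median moved by under 0.1 or a gene still past its threshold. Of the rest, 442 kept their direction without passing the threshold and 39 moved. Of the limma calls, 1 for LIF (Sprr2a2) and 221 for genotype passed in every fit they entered.

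No paired analysis was possible because the groups share only replicate number 1; the limma fits instead used genotype or treatment as the block. Leaving out a library was not possible, since each group has 1 and the additive fit would then have 0 residual degrees of freedom. At 22 to 27.5 M fragments, a single fragment on a 2 kb transcript is about 0.02 FPKM, so depth limits mainly genes near the filter.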

Other observations

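All values in this part are of lists or libraries fixed in advance, except the FPKM of Dcn, Cdh5 and Cma1, picked as examples after their values were seen. No test here was chosen after the result was seen.

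Libraries of the same genotype were the closest, with a Pearson r across genes of 0.994 between the wild-type pair and 0.995 between the Stat4-/- pair, on the log2 scale.

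Markers of other cell types were measurable in the libraries, some at high and some at low levels. In wild-type control, wild-type LIF, Stat4-/- control and Stat4-/- LIF, the fibroblast gene Dcn was at 127, 143, 136 and 140 FPKM. In the same order, the endothelial gene Cdh5 was at 52.3, 51.8, 60.8 and 65.3 FPKM, and the mast cell gene Cma1 at 2.46, 1.95, 0.87 and 1.23 FPKM. With limma, 5 of 11 genes of enteric glia and neurons were lower in Stat4-/- (6 adjusted over the list alone), as were 4 of 6 mast cell genes (4 lower and 1 higher adjusted over the list alone) and 3 of 4 red blood cell genes (3 adjusted over the list alone). Without a variance trend 1 call was left for enteric glia and neurons and 0 for mast cells and red blood cells. Of 20 fibroblast genes 1 was higher and 3 lower (2 and 3 adjusted over the list alone), of 17 macrophage genes 2 and 2 (2 and 2), of 5 neutrophil genes 1 and 1 (2 and 1), and of 8 T and NK genes 1 was higher (1).

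Of 12 stem cell genes 1 was lower in Stat4-/- by limma, Prom1 (1 adjusted over the list alone), and of 5 tuft cell genes Ptgs1 was lower (2 adjusted over the list alone). Of 18 fetal-like regeneration genes 3 were higher and 8 lower (3 and 10 adjusted over the list alone), while with LIF Ly6a was higher and Clu lower. Of 16 tight junction genes 4 were higher and 3 lower (4 and 3), of 20 antimicrobial and acute phase genes 2 and 4 (5 and 4), of 20 immediate early and heat shock genes 9 and 2 (10 and 3), of 22 glycolysis and hypoxia genes 1 and 1 (1 and 1), and of 25 oxidative phosphorylation genes 5 and 1 (6 and 1). No cell cycle gene of 22 was called for genotype by limma, and Pcna was higher with LIF. Of the 18 chromosome 1 neighbours of Stat4, 4 were higher and 4 lower (4 and 4 adjusted over the list alone). Without a variance trend, 0 genotype calls were left for the stem, tuft, fibroblast, neutrophil, glycolysis and hypoxia, and oxidative phosphorylation lists. Both tested sex-linked genes, Ddx3y and Eif2s3y, were lower.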
